A study of Arabidopsis thaliana with 21 samples.

How the data were processed

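RNA from fluorescence-sorted root protoplasts of Arabidopsis thaliana was measured by sequencing in 21 libraries of 6 reporter lines (n = 2 to 4 per line). Per the labels, roots of seedlings grown for 5 days were digested with cell wall enzymes, fluorescent cells were sorted, and cDNA was amplified by PCR from low RNA input. The deposited files hold 1 raw read count per gene and library, with no normalisation, for 33602 genes named by their Arabidopsis locus code. Per the submitters' processing notes, Bowtie2, featureCounts, edgeR and the TAIR10 build were used, in versions that are not given in the sources used here, and strand is not stated. Of the locus codes, 32835 were found in the reference names used here (TAIR10.1), which gave symbols only. The locus code carries the chromosome, and coordinates were not used.

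All libraries entered 1 model in edgeR 4.0.16 (R 4.3.3) with a coefficient per line, TMM scaling, the filterByExpr filter (26074 genes kept), robust quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.377. Each of 7 comparisons is a contrast of 2 lines in that model. A gene counted as enriched in a line when it was higher there than in each of the other 5. Levels are TMM-scaled counts relative to library size (CPM) with SD, and changes are log2 with the SE from the model.

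The lines compared, the tests, the alternatives, the rule for named genes and 17 gene lists were fixed before the data were examined. The lists are early protophloem, late sieve element, companion cell, xylem, procambium, pericycle, endodermis, epidermis and root hair, root cap, root stem cell niche, G2 and M phase, DNA replication, histone, ribosome biogenesis, autophagy, wounding and stress, and A-type response regulators. A list member was dropped where the reference gave its locus code a symbol and neither that symbol nor a listed synonym matched, which removed PEAR1, CALS8 and SGN3. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 119 tests, and again with an estimated correlation and with fry, which tests whether the genes of a set move on balance one way. With an estimated correlation no list was called in any comparison, and the lowest adjusted p was 0.255. Counts adjusted over the list alone are given where they differ from those over all genes. Named genes were, per comparison, the 8 higher and 8 lower with the largest change among genes past the test with a mean of at least 20 CPM in the higher line, a symbol, a nuclear locus and no overlap between libraries, the 6 reporter genes, and up to 4 members of each list with the smallest adjusted p. Chance gives no overlap in 2.86% of genes for 4 against 4 libraries, 5.71% for 4 against 3 and 13.3% for 4 against 2. WAVE2 was in that set by the rule, and its neighbours were looked up after its values were seen.

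Library totals ran from 23513921 to 36198012 counts. Where a line had 0 counts of a gene, the fold is a lower bound against 3 counts over the line, and for 1 to 3 counts a ratio is given with its 95% counting interval (exact binomial). Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Reads shared by near-identical genes, such as those of H2B, H3, H4 and the fibrillarins FIB1 and FIB2, limit how far counts separate the copies. The pipeline was tested on simulated data with 200 changed genes. For CALS7 against PEAR1 it recovered 11.9%, 41.8% and 72.7% of genes changed 2-, 4- and 8-fold, with 1.18% false calls. For PEAR1-DBOX against PEAR1, with 2 libraries on 1 side, these were 7.46%, 38.8% and 60.6%, with 2.74% false calls. The simulation changed genes in 1 line only, as many up as down, and gave all lines the same mean otherwise. In the data 74.4% of genes differed among the lines, so these rates may not carry over.

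The alternatives were median-of-ratios size factors (RLE), no filter, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, only the 2 lines compared, and each library left out in turn. When that left PEAR1-DBOX with 1 library, its spread was taken from the other lines. Fits with NAC73 1 and 4 only, NAC73 2 and 3 only, and PEAR1 1 and 3 only were added after the data were seen. Single values were scanned for outlying libraries in lines of 4, and for genes this was limited to lines with a mean of at least 20 CPM, a limit chosen after the data were seen. No library or sample was left out of the main comparisons. Sequence reads were not used, since the deposited files hold counts only, so reads on transgenes were not counted apart. Figures were drawn with matplotlib 3.10.9.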

Results

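The data are read counts per gene from RNA of fluorescent cells, sorted from root protoplasts of Arabidopsis thaliana seedlings grown for 5 days. The series describes the sorted cells as protophloem sieve elements, the sugar-conducting cells that mature first in the root phloem. There were 21 libraries from 6 reporter lines, and each line is named here by the promoter that drives its reporter. The PEAR1 line (n = 4) carried YFP under the promoter of PEAR1, a DOF transcription factor of early phloem cells. The PEAR1-DBOX line (n = 2) had the same promoter with a destruction box in the reporter, a motif that leads to degradation of a protein as mitosis ends. The CVP2-DBOX line (n = 4) had a destruction box reporter under the promoter of CVP2, a phosphoinositide phosphatase of developing sieve elements. The CALS7 line (n = 4) and the NAC73 line (n = 4) carried YFP fused to histone H2B under the promoters of CALS7, a callose synthase of sieve plates, and NAC073, a NAC transcription factor. Both also carried a red reporter under the S32 promoter. The NAC57 line (n = 3) carried GFP under the promoter of NAC057, another NAC transcription factor, and H2B-RFP under the CALS7 promoter. The labels state that fluorescent cells were collected and do not state which colour the gate used.

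Library totals ran from 26138629 to 31292379 counts in the PEAR1 line, 29839934 to 36163248 in PEAR1-DBOX, 33810116 to 36198012 in CVP2-DBOX, 26724330 to 30888884 in CALS7, 23513921 to 32260798 in NAC73 and 26117515 to 32519005 in NAC57. The number of genes with a count was highest in the PEAR1 line, at 30092 ± 588 (SD, n = 4), and lowest in the NAC73 line, at 18058 ± 1146 (SD, n = 4). The 2 PEAR1-DBOX libraries had counts on 22747 and 28322 genes. The first principal component held 42.5% of the variance and the second 17.7%. On the first component NAC73 2 and 3 stood at 352.2 and 371.8, NAC73 1 and 4 at 159.1 and 140.2, and the 4 CALS7 libraries near 100, while the other 13 libraries had negative scores. On the second, PEAR1-DBOX 3 stood at 78.5, within the range of CVP2-DBOX (37.4 to 102.7), and PEAR1-DBOX 5 at -76.8, nearer PEAR1 (-135.4 to -94.9). Separate cultures or plantings are not stated for the replicates, so each p-value measures only the spread between these libraries. No batch is given in the labels, and each reporter is named as a single line. Promoter, line, gate and handling therefore cannot be told apart in any comparison of lines.

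The gene whose promoter named the line was at its highest in the matching line for CVP2 and NAC073. CVP2 (AT1G05470) stood at 655 ± 53.4 CPM (read counts per gene scaled to library size; SD, n = 4) in the CVP2-DBOX line, 572 ± 62.6 (n = 3) in the NAC57 line and 178 to 269.6 in the other 4. NAC073 (AT4G28500) stood at 503 ± 159 CPM (n = 4) in the NAC73 line, 148 ± 36.9 (n = 4) in the CALS7 line and 14.3 or less elsewhere. CALS7 (AT1G06490) was at 3886 ± 566 CPM (n = 4) in the CALS7 line and 4204 ± 2214 (n = 4) in the NAC73 line, against 126 to 198 in the other 4 lines. PEAR1 (AT2G37590) was highest in the CVP2-DBOX line, at 474 ± 33.9 CPM (n = 4), and stood at 215 ± 40.5 (n = 4) in the PEAR1 line. The PEAR1-DBOX, CALS7 and NAC57 lines held it at 273.6, 299.1 and 310.2 CPM. Only the NAC73 line was lower than the PEAR1 line, at 187.8 CPM, so PEAR1 too was not high in the line named for it. S32 (AT2G18380) rose from 309 ± 45.3 CPM (n = 4) in the PEAR1 line to 957.5 ± 60.5 (n = 4) in CALS7 and was at 1477 ± 518 (n = 4) in NAC73. NAC057 (AT3G17730) was at 21.1 ± 9.62 CPM (n = 3) in the line labelled NAC57, the lowest of the 6 lines, against 434.5 ± 28.7 (n = 4) in CALS7 and 679 ± 238 (n = 4) in NAC73. This gene goes against the label, so directions given for that line are those of the line labelled NAC57.

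**Figure D1:**
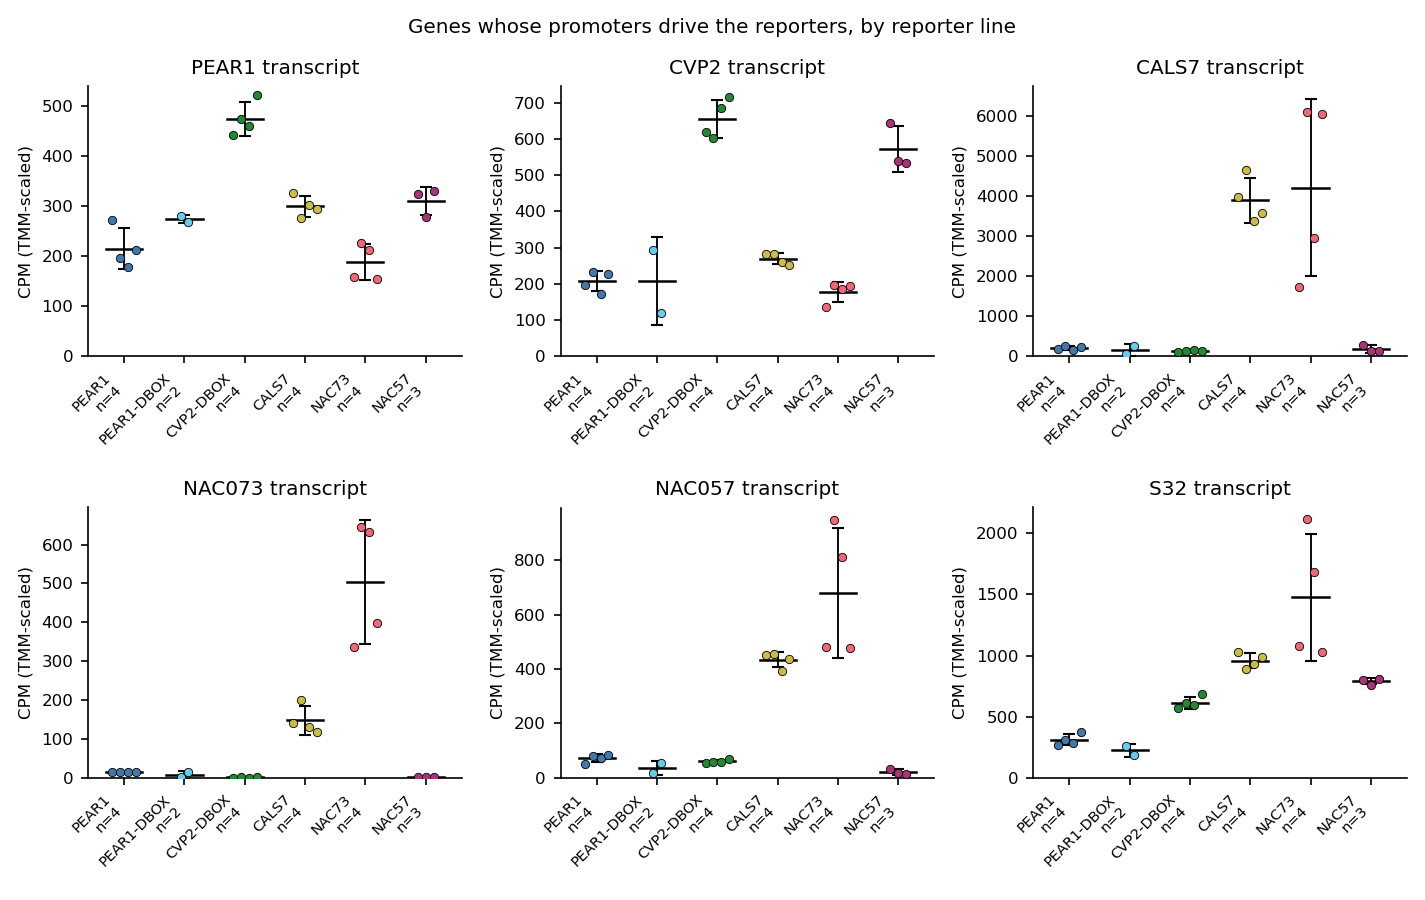
Normalised read counts (CPM) of the 6 genes whose promoters drive the reporters, with 1 point per library by line and bars for the mean and SD. CALS7 averages 3886 in the CALS7 line and 4204 in the NAC73 line, and NAC057 is lowest, at 21.1, in the line labelled NAC57.

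PEAR1-DBOX against PEAR1 asks what differs when the reporter under 1 promoter carries a destruction box. Some mitotic genes were higher with the destruction box (n = 2) than without (n = 4). CYCB1;3 (AT3G11520), a mitotic cyclin, rose 6.21-fold (log2 2.63 ± 0.31, SE), from 37.2 ± 8.54 to 231 ± 130 CPM (SD), and its log2 rise was 1.91 without PEAR1-DBOX 3. The Aurora kinase genes AUR1 and AUR2, whose products act in mitosis, rose 4.68-fold (log2 2.23 ± 0.27) and 4.44-fold (log2 2.15 ± 0.27), with 1.59 and 1.41 on the log2 scale without PEAR1-DBOX 3. DIN10, a gene induced in the dark, fell 7.88-fold (log2 -2.98 ± 0.36). CYCB1;1 (AT4G37490), the cyclin whose destruction box is widely used in such reporters, rose 17.9-fold (log2 4.16 ± 1.04), and that call ended when any 1 of the 6 libraries was left out, with log2 values from 3.83 to 4.48. Of 26 genes of G2 and M phase, 12 rose and 14 did not pass the test (24 rose adjusted over the list alone), with a median log2 change of 2.48 and adjusted p = 0.255 with an estimated correlation. Without PEAR1-DBOX 3 the G2 and M phase list had 3 genes that rose and a median of 1.63.

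Of the 18 early protophloem genes, BAM3, a receptor kinase, fell (log2 -1.10 ± 0.24) and 17 did not pass, with 2 lower adjusted over the list alone, a median of 0.09, a mean of 0.01 and a test that pointed down. The BAM3 call ended without PEAR1 2 (log2 -1.03), PEAR1-DBOX 3 (-1.27) or PEAR1-DBOX 5 (-0.95). The set test with a preset correlation called ribosome biogenesis (median log2 0.97, adjusted p = 0.568 with an estimated correlation) and root stem cell niche genes (1.59, adjusted p = 0.343 with an estimated correlation) higher. It called xylem (-0.95), pericycle (-2.25) and endodermis genes (-2.12) lower, with adjusted p = 0.694, 0.378 and 0.568 with an estimated correlation. These 3 calls ended without PEAR1-DBOX 3, where the medians were -0.36, -1.70 and -1.25. Pericycle (-3.36) and endodermis genes (-4.44) also lost their calls without PEAR1-DBOX 5, as did xylem genes without PEAR1 1 (-0.54) and endodermis genes without PEAR1 4 (-1.63). Without PEAR1-DBOX 3 the histone (-0.98), DNA replication (-0.84), early protophloem (-0.27) and epidermis and root hair lists (-4.67) were called lower. The histone list was also called without PEAR1 2 (-0.34), the epidermis and root hair list without PEAR1 1 (-5.85) or PEAR1 3 (-5.89), and the procambium list, as higher, without PEAR1 1 (0.84). No member of 15 lists passed edgeR's test, and adjusted over the list alone 3 late sieve element, 1 histone and 1 epidermis gene were lower and 1 procambium, 1 ribosome biogenesis and 1 wounding and stress gene higher. Of their 183 members, 29 had an unadjusted p below 0.05, DESeq2 called 16 and voom with sample weights called 13. PEAR1 2 and 4 and not PEAR1 1 and 3 held root hair transcripts, and the epidermis and root hair list had a median of -5.49 (-5.43 with members without counts at their bound), which was not called.

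In all, 366 genes were higher and 231 lower in PEAR1-DBOX, of 26074 tested, and with median-of-ratios size factors 206 were higher and 244 lower, with the median of all genes moved by -0.12. The total of 597 rested on single libraries: it was 30 without PEAR1-DBOX 3, 1543 without PEAR1-DBOX 5, 186 without PEAR1 2, 206 without PEAR1 3 and 344 without PEAR1 4. With PEAR1 1 and 3 only it was 26. Of 20 named genes past the test, 16 were not called without PEAR1-DBOX 3.

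CVP2-DBOX against PEAR1 sets the CVP2 promoter with a destruction box beside the PEAR1 promoter without it (n = 4 each). Mitotic genes were higher, and 12 of 21 wounding and stress genes lower, in the CVP2-DBOX line. CYCB1;1 rose 39.7-fold (log2 5.31 ± 1.02), from 19.1 ± 8.13 to 757 ± 100.2 CPM. PLE, a microtubule-associated protein of cytokinesis, rose 7.78-fold (log2 2.96 ± 0.30) and AUR1 5.70-fold (log2 2.51 ± 0.24). PAX, a protein kinase of protophloem development, rose 3.04-fold (log2 1.60 ± 0.17), from 158 ± 23.1 to 479 ± 45.8 CPM. NAC086, a NAC transcription factor that acts in enucleation of sieve elements, fell 8.79-fold (log2 -3.14 ± 0.37). Of 26 G2 and M phase genes, 25 rose and 1 did not pass (26 rose adjusted over the list alone), with a median log2 change of 2.82 and adjusted p = 0.255 with an estimated correlation.

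Of 18 early protophloem genes, 9 rose and 9 did not pass (11 rose adjusted over the list alone), with a median of 1.17 and adjusted p = 0.278 with an estimated correlation. Examples are the DOF transcription factor genes DOF6 (log2 1.26 ± 0.16) and TMO6 (1.17 ± 0.16). Of 14 late sieve element genes, 4 rose and 7 fell, among them NAC028 (log2 0.99 ± 0.14) and the exonuclease gene NEN1 (-2.23 ± 0.38). Of 19 histone genes 7 rose (4 without PEAR1 2 or PEAR1 3), such as HTB9 (log2 0.97 ± 0.18) and HTB11 (0.90 ± 0.19), with a median of 0.79 and adjusted p = 0.566 with an estimated correlation. In ribosome biogenesis, 2 of 13 genes rose (1 adjusted over the list alone), one of them ENP1 (log2 0.84 ± 0.19), with a median of 0.87 and adjusted p = 0.680 with an estimated correlation. DNA replication genes had a median near 0 (-0.00; mean 0.05, test up) and 1 of 20, CDT1B, rose (log2 1.96 ± 0.49). Of 11 autophagy genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with ATG8A at log2 -3.17 ± 0.42, a median of -1.34 and adjusted p = 0.159 for the set (0.0397 with fry, another set test). With median-of-ratios size factors 6 autophagy genes fell and 0 rose. Of 21 wounding and stress genes, 12 fell and 9 did not pass (13 fell adjusted over the list alone), with a median of -2.79 and adjusted p = 0.438 with an estimated correlation. They include TCH4 (log2 -2.79 ± 0.37) and WRKY18, which fell 26.9-fold (log2 -4.75 ± 0.72).

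Xylem genes fell in CVP2-DBOX against PEAR1 in 7 of 18 cases (9 adjusted over the list alone; median -3.30, adjusted p = 0.568 with an estimated correlation), pericycle genes in 3 of 6 (median -3.62, adjusted p = 0.343 with an estimated correlation) and companion cell genes in 1 of 9 (median -2.80, adjusted p = 0.550 with an estimated correlation). The pericycle number was 1 or 2 without any 1 library of the 2 lines. PHO1, a phosphate exporter of the stele, stood at 246 CPM in the PEAR1 line and 4.4 in CVP2-DBOX (log2 -5.79 ± 1.16). Of 13 epidermis and root hair genes 4 fell (6 adjusted over the list alone), a number that was 1 or 2 without any 1 library of the 2 lines but PEAR1 1, while PEAR1 2 and 4 held root hair transcripts. Of 11 endodermis genes 2 fell (4 adjusted over the list alone; 0 without CVP2-DBOX 1 or CVP2-DBOX 4), a list called with fry (adjusted p = 0.00850) and, with the preset correlation, only without PEAR1 2 (-2.35), and of 8 procambium genes PXY, a receptor kinase gene, rose (log2 1.17 ± 0.23). Of 10 A-type response regulators, which respond to cytokinin, 4 fell (5 adjusted over the list alone), with ARR4 at log2 -2.06 ± 0.24, a median of -1.40 and adjusted p = 0.568 with an estimated correlation. That set call ended without PEAR1 2 (-1.32), PEAR1 3 (-0.72), CVP2-DBOX 3 (-1.31) or CVP2-DBOX 4 (-1.38). No root cap or root stem cell niche gene passed edgeR's test, and of their 10 members 1 had an unadjusted p below 0.05, DESeq2 called 1 and voom called 5. The niche median was 0.55 and its mean -0.16. In all, 3185 genes were higher and 3957 lower, and of 65 named genes past the test 13 were not called without 1 of the libraries, 11 of them without CVP2-DBOX 1. Size factors by median of ratios moved the median of all genes by -0.13, with 2433 genes higher and 4253 lower. There were 6950 higher and 8271 lower with voom, and 6319 higher and 6275 lower with only the 2 lines fitted.

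CVP2-DBOX against PEAR1-DBOX compares 2 promoters with the same kind of reporter (n = 4 and n = 2). In the CVP2-DBOX line 9 of 18 early protophloem genes were higher and 11 of 21 wounding and stress genes lower. BAM3 rose 3.05-fold (log2 1.61 ± 0.25), from 297 ± 45.7 to 905.5 ± 117 CPM, and PAX 2.74-fold (log2 1.45 ± 0.21). NPY3, an NPH3-domain gene, rose 4.52-fold (log2 2.17 ± 0.28), from 50.01 ± 15.8 to 226 ± 13.4 CPM. TCH4, a xyloglucan endotransglucosylase gene induced by touch, fell 19.9-fold (log2 -4.32 ± 0.43). CVP2 itself rose by 1.66 ± 0.26 on the log2 scale, and by 2.44 without PEAR1-DBOX 3. Of 18 early protophloem genes, 9 rose and 9 did not pass (11 rose adjusted over the list alone; median 0.88, adjusted p = 0.255 with an estimated correlation). Of 19 histone genes 5 rose, such as HTB11 (log2 1.80 ± 0.25) and HTB9 (1.56 ± 0.23), with a median of 0.99 and adjusted p = 0.422 with an estimated correlation.

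Of 21 wounding and stress genes, 11 fell and 10 did not pass (15 fell adjusted over the list alone; median -2.61, adjusted p = 0.255 with an estimated correlation). Of 11 autophagy genes, 5 fell (9 adjusted over the list alone), such as ATG8H (log2 -2.47 ± 0.37), with a median of -1.50 and adjusted p = 0.566 with an estimated correlation. Late sieve element genes went both ways, with 3 up, such as NAC020 (log2 1.49 ± 0.21), 7 down and 4 not past the test (4 up and 7 down adjusted over the list alone), a median of -0.75, a mean of -1.49 and a test that pointed up. The 26 G2 and M phase genes had a median of 0.42 and none passed, and the set call (adjusted p = 0.654 with an estimated correlation) ended without PEAR1-DBOX 5, where the median was -0.08. The stem cell niche list fell as a set (median -1.04, adjusted p = 0.455 with an estimated correlation), with WOX5 lower and 4 not past, and without PEAR1-DBOX 3 its median was -0.65 and the call ended. The WOX5 call (log2 -4.42 ± 1.14) ended without any 1 of the libraries but CVP2-DBOX 4 (-5.68), with log2 values from -4.44 to -4.07. Of 18 xylem genes 2 fell and of 10 A-type response regulators 3 fell (4 and 4 adjusted over the list alone), and of 9 companion cell genes 1 fell. None of these lists was called as a set, but without PEAR1-DBOX 3 all 3 were, with medians of -3.22, -1.92 and -2.88. The 2 xylem genes, XCP1 and XCP2, lost their calls without any 1 of the CVP2-DBOX libraries and turned to 6.48 and 5.92 without PEAR1-DBOX 5, where the 3 response regulators also lost theirs. The DNA replication list was also called without PEAR1-DBOX 3, at 0.79. Of 94 members of the 7 lists in which edgeR called no gene, 1 pericycle gene was lower adjusted over the list alone, 4 had an unadjusted p below 0.05, DESeq2 called 3 and voom 3. Median, mean and test differed in sign for the endodermis (-0.58, -0.05, up) and root cap lists (0.12, -0.07, up). In all, 1008 genes were higher and 2122 lower, a total of 3130 that was 1458 without PEAR1-DBOX 5. Without PEAR1-DBOX 5, 6 early protophloem and 3 histone genes rose, and 6 wounding and stress, 2 autophagy and 1 late sieve element genes fell. Of 49 named genes past the test 15 were not called without 1 of the libraries, 14 of them without PEAR1-DBOX 5, among them ATG8A (-2.60, then -1.26) and ATG8B.

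CALS7 against PEAR1 sets cells of a sieve element differentiation promoter beside those of an early phloem promoter (n = 4 each). Genes of late sieve element development were higher in the CALS7 line, and genes of division, DNA replication and ribosome assembly were lower. NAC086 rose 13.4-fold (log2 3.74 ± 0.38), from 149 ± 31.1 to 1996 ± 313 CPM, and NEN2, an exonuclease gene that acts in nuclear degradation, 11.1-fold (log2 3.48 ± 0.31). CALS7 rose 19.6-fold (log2 4.29 ± 0.50) and BRX, a membrane-associated regulator of protophloem differentiation, 8.02-fold (log2 3.00 ± 0.21), from 102 ± 13.4 to 821 ± 74.3 CPM. PLE fell 9.26-fold (log2 -3.21 ± 0.30) and PCNA2, a replication clamp gene, 16.2-fold (log2 -4.02 ± 0.69). HTB2 (AT5G22880), a histone H2B gene, rose 45.3-fold (log2 5.50 ± 0.30), from 197 ± 50.5 to 8907 ± 3097 CPM, in a line whose reporter is an H2B fusion. Of 14 late sieve element genes, 12 rose and 2 did not pass, with a median log2 change of 3.37 and adjusted p = 0.255 with an estimated correlation.

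Of 26 G2 and M phase genes, 25 fell and 1 rose (median -3.17, adjusted p = 0.633 with an estimated correlation), and of 20 DNA replication genes, 18 fell (19 adjusted over the list alone), such as TSO2, a ribonucleotide reductase gene (log2 -2.91 ± 0.41), with a median of -2.96. Of 13 ribosome biogenesis genes, 12 fell (13 adjusted over the list alone, 6 without CALS7 1, CALS7 3 or CALS7 4; median -3.41), and of 19 histone genes 17 fell and HTB2 rose (median -3.33). These 3 lists each had adjusted p = 0.568 with an estimated correlation. Of 11 autophagy genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), such as ATG8H, which rose 6.96-fold (log2 2.80 ± 0.33), with a median of 0.77 and adjusted p = 0.568 with an estimated correlation. Early protophloem genes were divided, with 6 up, 4 down and 8 not past the test (median 0.10, mean -0.35, test up). All 5 stem cell niche genes fell, such as PLT2 (log2 -3.55 ± 1.05), with a median of -3.55 and adjusted p = 0.545 with an estimated correlation. Of 21 wounding and stress genes, 12 fell (median -2.25, adjusted p = 0.654 with an estimated correlation), with WRKY18 at log2 -4.00 ± 0.69. Among A-type response regulators 2 rose and 3 fell (median 0.24, mean -0.41), with ARR4 up 4.86-fold (log2 2.28 ± 0.24).

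Of 8 procambium genes 3 rose in CALS7 against PEAR1, such as PXY (log2 2.57 ± 0.24), and 2 fell (3 and 3 adjusted over the list alone; median -0.90, test up). AHA3, a proton pump of companion cells, rose 9.35-fold (log2 3.22 ± 0.37) and 1 other companion cell gene fell (1 and 4 adjusted over the list alone; median -1.80). In the remaining lists, 3 xylem genes (2 adjusted over the list alone), 2 pericycle genes, 1 endodermis gene (MGP) and 1 epidermis gene (CPC; list median 0.34, test down) fell. No root cap gene passed edgeR's test, 0 of its 5 members had an unadjusted p below 0.05, DESeq2 called 0 and voom called 1. CALS7 2 held root hair transcripts, such as EXT13 at 216 CPM. In all, 3845 genes were higher and 6034 lower, and MYB28, a regulator of glucosinolate synthesis, was at least 1609-fold lower in CALS7, where it had no counts. Median-of-ratios size factors moved the median of all genes by 0.12, and of 73 named genes past the test 5 were not called without 1 of the libraries.

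NAC73 against CALS7 compares 2 lines with the same H2B-YFP and S32 reporters and different first promoters (n = 4 each). Autophagy genes were higher in the NAC73 line and early protophloem genes lower. The exonuclease gene NEN1 rose 4.84-fold (log2 2.27 ± 0.38), from 763 ± 202 to 3692 ± 1247 CPM, and NEN2 3.88-fold (log2 1.96 ± 0.29). ATG8H, of the autophagosome, rose 4.89-fold (log2 2.29 ± 0.32), from 236 ± 35 to 1155 ± 652 CPM. The receptor-like protein gene RLP12 rose 14.8-fold (log2 3.89 ± 0.68), from 10.97 ± 4.99 to 163 ± 73.8 CPM. PEAR2, a DOF transcription factor gene, fell 3.04-fold (log2 -1.60 ± 0.27). HTB2 fell 18.9-fold (log2 -4.24 ± 0.28), although both lines carry an H2B reporter. NAC073 rose 3.41-fold (log2 1.77 ± 0.63), a call that ended without CALS7 1, CALS7 3, CALS7 4, NAC73 2 or NAC73 3, with log2 values of 1.75, 1.71, 1.68, 1.63 and 1.64.

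Of 11 autophagy genes, 9 rose and 2 did not pass (median log2 1.64, adjusted p = 0.343 with an estimated correlation). Of 14 late sieve element genes, 5 rose, 3 fell, such as NAC020 (log2 -0.79 ± 0.16), and 6 did not pass (median 1.15, adjusted p = 0.568 with an estimated correlation). Of 18 early protophloem genes, 12 fell and 1 rose, with PAX at log2 -1.16 ± 0.16 and DOF6 at -1.19 ± 0.16, a median of -0.80 and adjusted p = 0.422 with an estimated correlation. Of 21 wounding and stress genes 8 fell (17 without NAC73 1), such as TCH4 (log2 -2.51 ± 0.38), with a median of -1.25 and adjusted p = 0.568 with an estimated correlation. Of 19 histone genes, 15 rose and HTB2 fell (17 and 1 adjusted over the list alone), such as HTB11, which rose 3.22-fold (log2 1.69 ± 0.19), with a median of 1.70 and adjusted p = 0.598 with an estimated correlation.

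The replicates of the NAC73 line differed in genes of DNA replication, ribosome biogenesis, histones and stress. Summed over the DNA replication list, NAC73 1 and 4 had 780.9 and 716 CPM, and NAC73 2 and 3 had 69.6 and 90.9. Summed over the ribosome biogenesis list they had 1970 and 2135 against 224 and 246 CPM. Over the G2 and M phase list without CYCB1;1 the sums were 268 and 413.7 in NAC73 1 and 4 against 327.8 and 426.4 CPM in NAC73 2 and 3. Such sums weigh the most abundant genes, and like sums do not mean like levels over the list. The mean log2 CPM of the whole list was lower in NAC73 2 and 3, as given below. Over all 4 libraries, 8 of 20 DNA replication genes rose against CALS7 (median 1.72), 3 of 13 ribosome biogenesis genes rose (2.01) and 6 of 26 G2 and M phase genes rose and 1 fell (5 and 1 adjusted over the list alone; 0.28), and no set call was made for these lists. With single libraries left out, 3 to 14 DNA replication and 2 to 8 ribosome biogenesis genes rose. Without NAC73 2 or NAC73 3 the ribosome biogenesis list was called, with a median of 2.42 in both cases, and without NAC73 2 the DNA replication list was, at 2.10. The mean of the histone list was 6.01, 2.77, 4.34 and 5.10 log2 CPM in NAC73 1 to 4, against 3.27 to 3.74 in CALS7, so NAC73 2 lay below each CALS7 library. With NAC73 2 and 3 only, 5 histone genes rose and 3 fell, with a median of 0.44. The mean of the wounding and stress list was 3.26, 0.90, -1.20 and 1.95 in NAC73 1 to 4, against 3.22 to 4.25 in CALS7. Other lists were also higher in NAC73 1 and 4 than in NAC73 2 and 3, in log2 CPM: root cap (4.31 and 2.20 against -0.49 and -2.35), stem cell niche (2.04 and 2.56 against 0.05 and -2.36), G2 and M phase (1.65 and 3.31 against -0.09 and 0.24), procambium (2.04 and 2.92 against 1.41 and 0.92), pericycle (-1.58 and -0.77 against -2.61 and -3.49) and early protophloem (4.94 and 5.93 against 4.74 and 4.33). The companion cell list (1.28 and 0.14 against -0.21 and -0.91) and the A-type response regulators (1.34 and 1.47 against 0.885 and 1.27) were also higher in NAC73 1 and 4. The autophagy (5.99 and 6.17 against 6.87 and 7.01) and late sieve element lists (9.08 and 9.63 against 10.0 and 9.88) were lower in NAC73 1 and 4. The 50 most abundant genes took 16.8% to 24.6% of the counts in NAC73 libraries, against 13.4% to 15.5% in CALS7.

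Among markers of other cells, 5 of 13 epidermis and root hair genes fell and 1 rose (6 and 1 adjusted over the list alone; median -5.15). CALS7 2 held root hair transcripts, with a mean of 3.40 log2 CPM over that list against -1.60, -1.79 and -0.09 in CALS7 1, 3 and 4 and -2.46 to -1.13 in NAC73. The number that fell was 2 without CALS7 2, where the list median was -0.04, 2 without NAC73 1 or NAC73 2, 3 without NAC73 3 and 0 with only the 2 lines fitted. In NAC73 vs CALS7, 3 of 18 xylem genes fell (6 without NAC73 4; median -1.10) and 2 of 9 companion cell genes fell (1 adjusted over the list alone; median 0.58, mean -1.08). Of the procambium genes PXY rose (log2 1.52 ± 0.23) and 3 fell, among stem cell niche genes BBM and PLT1 rose and WOX5 fell, and among A-type response regulators 2 rose and 1 fell (2 and 0 adjusted over the list alone; median -0.23, test up). With NAC73 2 and 3 only, BBM (log2 4.69) turned to -5.27 and the PLT1 and WOX5 calls ended, and all 3 calls ended with voom. In the endodermis, pericycle (median 0.31, mean -0.19) and root cap lists, of 22 members, none passed edgeR's test, 0 had an unadjusted p below 0.05, DESeq2 called 0 and voom 2. In all, 4077 genes were higher and 5286 lower in NAC73 and median-of-ratios size factors moved the median of all genes by -0.16. With only the 2 lines fitted there were 955 higher and 1302 lower. With NAC73 1 and 4 only there were 4947 higher and 3082 lower, and with NAC73 2 and 3 only 4357 higher and 7930 lower. Of 69 named genes past the test, 20 were not called without 1 of the libraries.

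NAC57 against CALS7 sets a line with 2 reporters, under the NAC057 and CALS7 promoters, beside the CALS7 line (n = 3 and n = 4). Genes of division were higher and genes of late sieve elements lower in the line labelled NAC57. PLE rose 25.0-fold (log2 4.64 ± 0.33), AUR1 8.11-fold (log2 3.02 ± 0.25) and the histone gene HTB9 6.05-fold (log2 2.60 ± 0.19). NEN1 fell 41.6-fold (log2 -5.38 ± 0.50), NAC086 fell by 4.46 ± 0.45 on the log2 scale and BRX fell 4.30-fold (log2 -2.10 ± 0.23). CALS7 fell 22.3-fold (log2 -4.48 ± 0.57) and NAC057 20.6-fold (log2 -4.37 ± 0.40), although both promoters drive reporters in this line. PEAR2 rose 4.37-fold (log2 2.13 ± 0.29) and CVP2 2.12-fold (log2 1.08 ± 0.21). WAVE2, of the complex that activates actin nucleation, had 1 count over the 3 NAC57 libraries, a ratio of 20110 (95% counting interval 3609 to 794300) below CALS7, and without NAC57 2 its log2 change was -15.66 against -13.84 ± 0.47.

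Of 26 G2 and M phase genes, 25 rose and 1 did not pass (median log2 4.24, adjusted p = 0.343 with an estimated correlation). Of 20 DNA replication genes, 18 rose (19 adjusted over the list alone), with MCM5, a subunit of the replicative helicase, at log2 3.03 ± 0.49, a median of 3.17 and adjusted p = 0.528 with an estimated correlation. Of 19 histone genes, 17 rose and HTB2 fell (18 and 1 adjusted over the list alone; median 4.16, adjusted p = 0.343 with an estimated correlation). Of 13 ribosome biogenesis genes, 10 rose (13 adjusted over the list alone, 6 without CALS7 1, CALS7 3 or CALS7 4; median 2.86, adjusted p = 0.568 with an estimated correlation). Of 14 late sieve element genes, 10 fell and 1 rose (median -4.21, adjusted p = 0.422 with an estimated correlation). Of 18 early protophloem genes, 10 rose and BRX fell (11 and 1 adjusted over the list alone; median 0.88, adjusted p = 0.455 with an estimated correlation), and with median-of-ratios size factors 8 rose and 2 fell. Autophagy genes went both ways, with 2 up and 3 down, ATG8A at log2 -3.36 ± 0.47 (median -0.22), and 0 up and 4 down with median-of-ratios size factors.

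Of 18 xylem genes 5 fell (4 adjusted over the list alone; 1 without NAC57 4), of 10 A-type response regulators 4 fell (2 without NAC57 1 or NAC57 4), such as ARR4 (log2 -2.52 ± 0.27), and 1 rose, and of 8 procambium genes PXY (-1.60) and PHB (-2.48) fell. Single markers passed in the companion cell (1 up, 2 down; median 0.02, mean -0.18), pericycle (PHO1 up), epidermis (1 up, 1 down, and 2 up and 1 down without CALS7 2, which held root hair transcripts), root cap (1 down, 0 adjusted over the list alone), stem cell niche (1 up, 1 down) and wounding and stress lists (1 down; median -0.46). PHO1 rose by 5.86 on the log2 scale, and by 6.62 without CALS7 1. No endodermis gene passed edgeR's test, 0 of its 11 members had an unadjusted p below 0.05, and DESeq2 and voom called 0. In all, 6295 of 26074 genes were higher and 6655 lower, and the numbers of xylem and procambium genes that fell are near that share. With median-of-ratios size factors, which moved the median of all genes by -0.41, 4240 were higher and 8554 lower. The directions above are relative to that shift, and of 67 named genes past the test 8 were not called without 1 of the libraries.

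NAC57 against NAC73 compares the lines named for the 2 NAC promoters (n = 3 and n = 4). Early protophloem and division genes were higher and late sieve element and autophagy genes lower in the line labelled NAC57. PEAR2 rose 13.3-fold (log2 3.73 ± 0.31) and PAX 4.25-fold (log2 2.09 ± 0.18). CDC20.1, an activator of the anaphase-promoting complex, rose 27.4-fold (log2 4.78 ± 0.50) and AUR1 5.87-fold (log2 2.55 ± 0.25). NEN1 fell 201.2-fold (log2 -7.65 ± 0.56), NEN2 45.2-fold (log2 -5.50 ± 0.38) and ATG8H 21.6-fold (log2 -4.43 ± 0.40). NAC057 fell 32.3-fold (log2 -5.01 ± 0.42). SHP2, a MADS-box gene, had no counts in the NAC57 libraries and was at least 1236-fold lower.

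Of 26 G2 and M phase genes, 25 rose and 1 fell (median log2 3.71, adjusted p = 0.343 with an estimated correlation). Of 19 histone genes 15 rose (15 and 1 lower adjusted over the list alone; median 2.33, adjusted p = 0.545 with an estimated correlation) and of 20 DNA replication genes 5 rose (3 adjusted over the list alone), such as CDT1A (log2 1.70 ± 0.30), with a median of 1.57 and adjusted p = 0.605 with an estimated correlation. The NAC73 replicates were divided in that list, at 4.56 and 4.70 log2 CPM in NAC73 1 and 4 and -0.49 and 0.22 in NAC73 2 and 3, against 5.25 to 5.63 in NAC57. In NAC57 vs NAC73, 3 DNA replication genes rose with NAC73 1 and 4 only (median 0.61), 19 with NAC73 2 and 3 only (4.99) and 1 with only the 2 lines fitted (1.44). Of 18 early protophloem genes, 13 rose and BRX fell (15 and 1 adjusted over the list alone), with a median of 1.96 and adjusted p = 0.343 with an estimated correlation. Of 14 late sieve element genes, 11 fell and 3 rose (median -5.26, adjusted p = 0.343 with an estimated correlation). Of 11 autophagy genes, 8 fell (8 and 1 higher adjusted over the list alone; median -1.97, adjusted p = 0.438 with an estimated correlation). The ribosome biogenesis list was called higher (median 0.92, adjusted p = 0.789 with an estimated correlation) with no member past the test, and the call ended without NAC73 2 (0.51) or NAC73 3 (0.51). The wounding and stress list was called higher, with 6 up and 1 down (14 up without NAC73 1), TCH4 at log2 2.35 ± 0.40, a median of 0.79 and adjusted p = 0.760 with an estimated correlation, and that call ended without NAC73 2 (0.60), NAC73 3 (0.37), NAC73 4 (0.80) or NAC57 1 (0.54).

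Of 10 A-type response regulators 2 fell, with ARR4 down 10.8-fold (log2 -3.43 ± 0.28; list median 0.17, mean -0.40, -0.31 with members without counts at their bound). The procambium genes PXY (log2 -3.13) and PHB (-2.84) fell and 1 rose (list median 0.49, test down), 2 xylem genes fell (0 adjusted over the list alone), and 2 companion cell genes rose and AHA3 fell (-2.12). In the pericycle 1 gene rose, in the epidermis CPC rose (log2 2.79) and 1 fell (1 and 0 adjusted over the list alone), and in the root cap 1 fell. In the 3 lists where edgeR called no gene, of ribosome biogenesis, the endodermis (median -0.69, test up) and the stem cell niche (median -0.17, test up), 0 of 29 members had an unadjusted p below 0.05, DESeq2 called 1 and voom 14. In all, 5576 genes were higher and 4155 lower, and with median-of-ratios size factors, which moved the median of all genes by -0.26, 4399 were higher and 4902 lower. With NAC73 1 and 4 only the total was 8069 and with NAC73 2 and 3 only it was 13384. With only the 2 lines fitted 1826 genes were higher and 3286 lower. Of 63 named genes past the test, 5 were not called without 1 of the libraries.

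**Figure D2:**
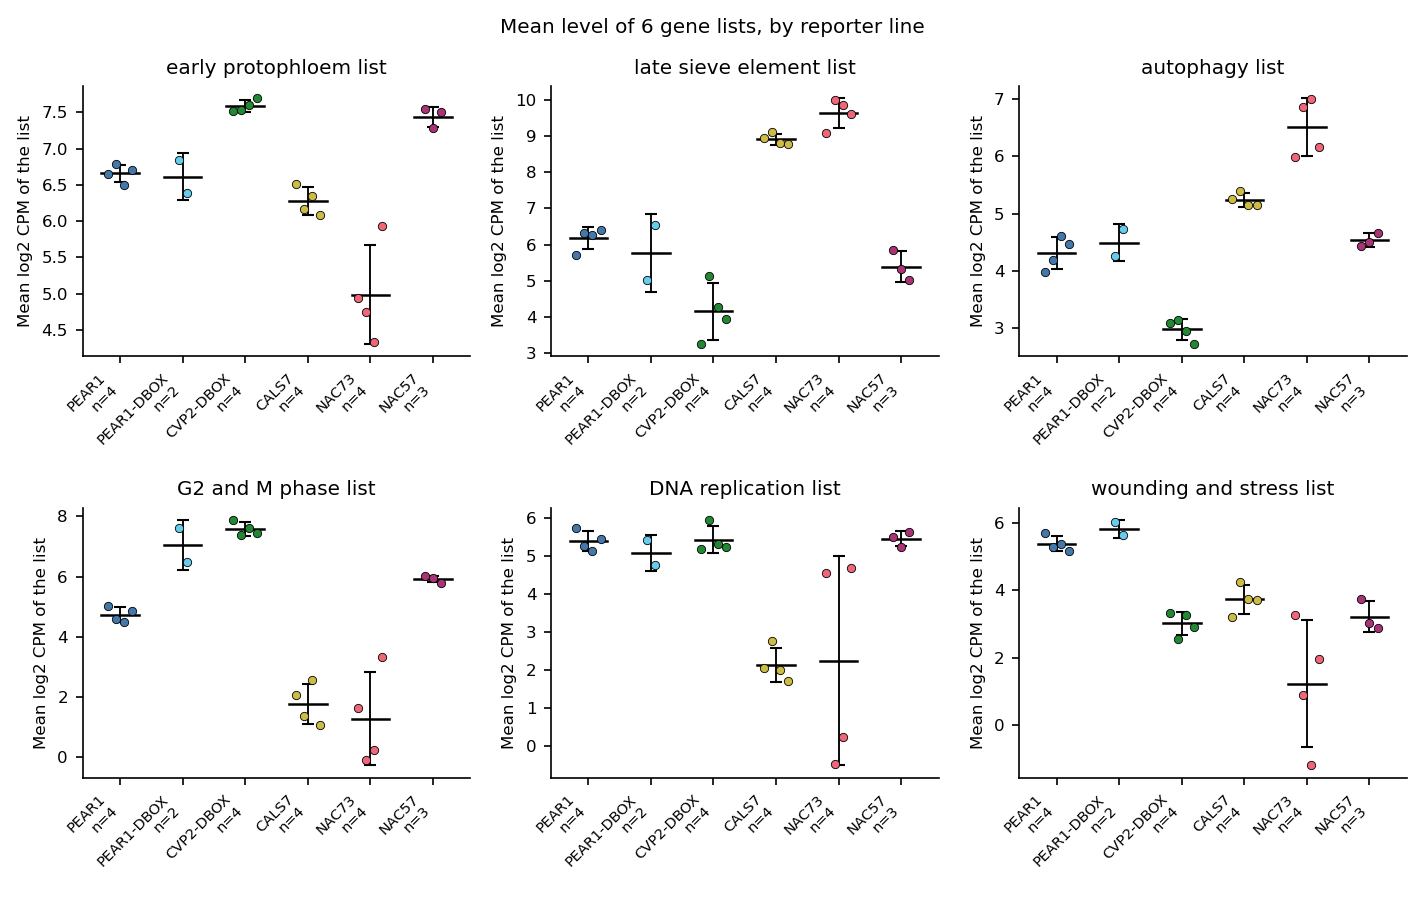
Mean log2 CPM of 6 gene lists in each of the 21 libraries, with 1 point per library by line and bars for the mean and SD. The late sieve element and autophagy lists are highest in the NAC73 line, and the G2 and M phase list is lowest in the CALS7 and NAC73 lines.

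**Figure D3:**
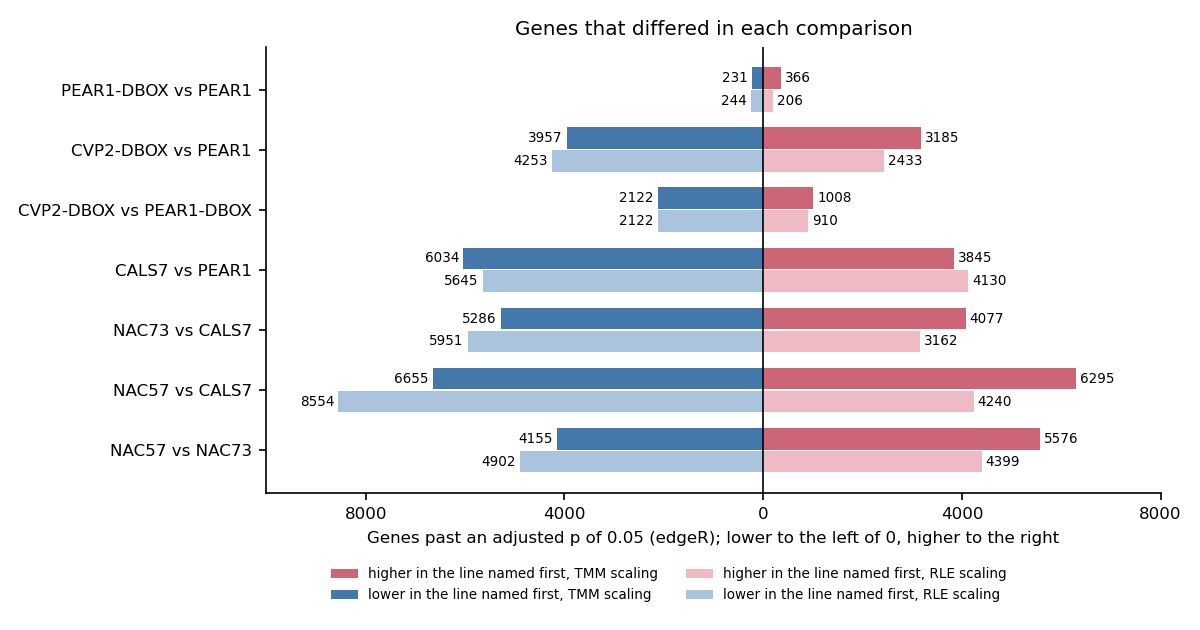
Number of genes past adjusted p 0.05 that were higher or lower in each of the 7 comparisons, by edgeR with TMM and with median-of-ratios size factors (RLE). NAC57 against CALS7 has the most, 6295 higher and 6655 lower with TMM and 4240 and 8554 with RLE.

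Over the 6 lines, 19390 of 26074 genes (74.4%) differed. Genes higher in 1 line than in each of the other 5 numbered 2626, of which 2311 were of the NAC73 line and 61 of the CALS7 line (117 with median-of-ratios size factors). The NAC73 number was 1268 with NAC73 1 and 4 only, 3068 with NAC73 2 and 3 only and 1386 with PEAR1 1 and 3 only. The numbers for the other 4 lines were lower than 2311 and moved by over 1.5 times when single libraries were left out, so they are not given. In the NAC73 line, NAC084, a NAC transcription factor gene, was higher than in the nearest line by 3.64 on the log2 scale, and ENODL20, an early nodulin-like gene, by 3.42. In the CALS7 line, HTB2 was higher than in the nearest line by 4.24 and AOX1A, the alternative oxidase of mitochondria, by 1.58, at 223 ± 26.0 CPM (SD, n = 4). In the NAC57 line, DRB5, a double-stranded RNA-binding protein gene, stood at 54.1 ± 8.3 CPM (SD, n = 3), 1.46 above the nearest line on the log2 scale. These 5 genes kept that place when each of the 21 libraries was left out in turn. TOPII, the type II DNA topoisomerase gene, was highest in CVP2-DBOX at 755 ± 106 CPM (SD, n = 4) against 369 in the next line. Without PEAR1-DBOX 5 it was no longer called higher there than in each of the other lines. BRG1 was highest in the PEAR1 line, at 117 ± 20.3 CPM (SD, n = 4) against 19.7 in the next, and FAD7, a fatty acid desaturase gene, in PEAR1-DBOX, by 1.59 on the log2 scale. Neither of these 2 was called without PEAR1-DBOX 3.

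**Figure D4:**
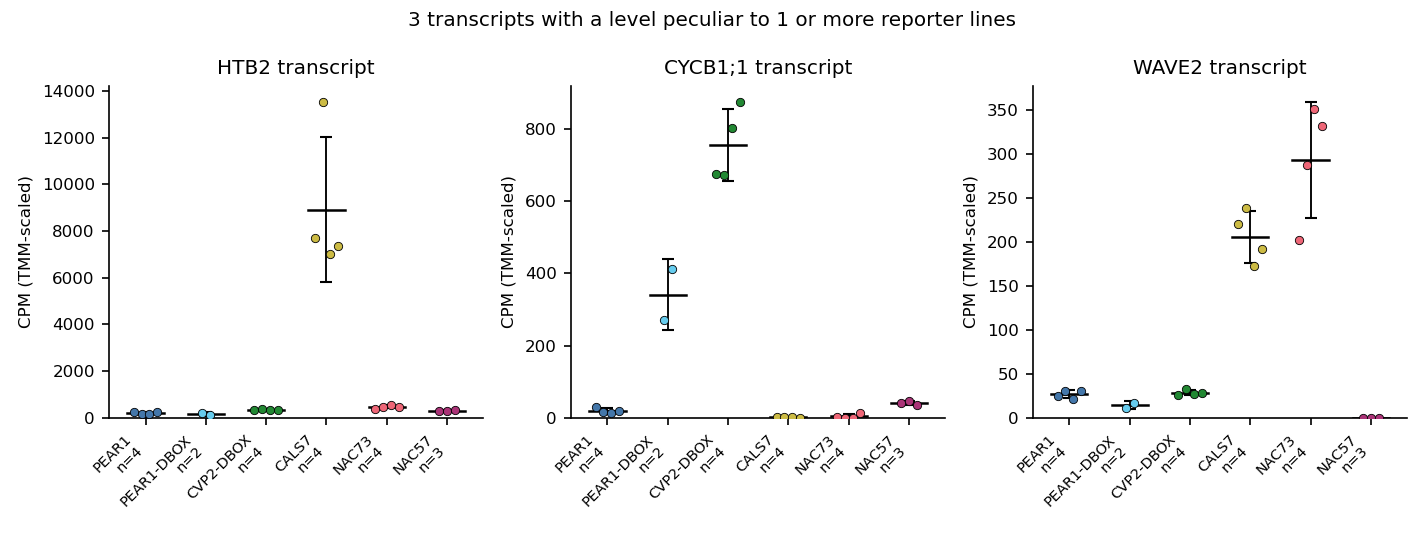
Normalised read counts (CPM) of HTB2, CYCB1;1 and WAVE2 in each of the 21 libraries, with 1 point per library by line and bars for the mean and SD. HTB2 averages 8907 in the CALS7 line and 197 in the PEAR1 line, and WAVE2 had 1 count over the 3 NAC57 libraries.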

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

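The tests of reporter reads pooled over lines and of other splits of the libraries were fixed before the result was seen, and those of HTB2 in single lines, of the NAC57 libraries, of WAVE2 and of the NAC73 replicates were chosen after it was seen.

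HTB2 was high in the CALS7 line, which has an H2B reporter, and CYCB1;1 in the lines with a destruction box reporter. In the NAC57 line, which also has an H2B reporter, HTB2 was at 280.2 to 310.1 CPM. That was below the 321.3 to 362.5 CPM of CVP2-DBOX, which has no H2B reporter. HTB2 was higher by 2.30 ± 0.17 (log2, SE) in the 3 lines with an H2B reporter than in the other 3, against 0.35 ± 0.12 for the next H2B gene (HTB11), which is consistent with reads of the fusion counted on HTB2 and rests mainly on the CALS7 line. A rise of the H2B genes together is argued against in that line, where the other H2B genes had a median change of -1.22 and a highest of -0.81 against PEAR1. In the NAC73 line HTB2 was higher by 1.26 ± 0.25 (HTB11 0.88 ± 0.19) and in NAC57 by 0.60 ± 0.26 (HTB9 1.16), so in these lines reads of the fusion and the endogenous gene cannot be told apart. The same is open for CYCB1;1, since the labels do not name the source genes of either fusion. It was higher by 5.96 ± 0.61 in the destruction box lines, against 4.57 ± 0.67 for CYCB1;4. The other CYCB1 genes rose there by 3.08 to 4.57, as more dividing cells would give. How much of the CYCB1;1 rise comes from dividing cells and how much from reads of the fusion was not tested.

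In the line labelled NAC57 the NAC057 gene was low and WAVE2 had 1 count. A swap with CALS7 or NAC73 is argued against, since it would put CALS7 at 174 or NAC073 at 2.08 CPM under its own promoter's label. A swap with PEAR1, PEAR1-DBOX or CVP2-DBOX cannot be told from NAC057. Its highest level in the 10 libraries of those lines, 84.28 CPM, was far below the lowest of CALS7 and NAC73, 393.6. That speaks against such a swap only if NAC57 cells hold NAC057 near the level of CALS7 and NAC73, which is not known. The excess of CYCB1;1 over the other CYCB1 genes was at most -1.73 in NAC57 libraries and at least -0.94 in the destruction box libraries. This sets the NAC57 libraries apart from those libraries. It speaks against libraries of a destruction box line under this label only if reads of the fusion are counted on CYCB1;1, which is open. A sort of cells in which the CALS7 promoter is not yet active may remain open, because the gate is not given. CALS7 was at 281.3 CPM or less in the NAC57 libraries against 3360 or more in the CALS7 line. A deletion that reaches the nearest expressed genes is argued against by their counts, 4904 for AT1G29220 and 26342 for ATS9. These lie 7 and 2 genes from WAVE2 in the order of locus codes. Genes between them and WAVE2 were not examined, so a smaller deletion remains open. A lesion within WAVE2 in this line cannot be told apart from absence of the transcript, with 1 count and no reads, and a difference between the lines' cells was not tested.

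The NAC73 libraries differed in genes of DNA replication and ribosome biogenesis, high in NAC73 1 and 4 and low in NAC73 2 and 3. Whether NAC73 1 and 4 held cells like those of the PEAR1, PEAR1-DBOX, CVP2-DBOX or NAC57 lines cannot be told, since 2 measures differ. The log2 ratio of summed G2 and M phase to DNA replication CPM was at most -0.79 in these 2 libraries. It was at least -0.47 in the 13 libraries of those lines, which goes against such cells. The sums in that ratio weigh the most abundant genes, while a mean of log2 CPM weighs each gene alike. The mean log2 CPM of the G2 and M phase list was higher in NAC73 1 and 4 (1.65 and 3.31) than in NAC73 2 and 3 (-0.09 and 0.24), as such cells would give. Lower depth of NAC73 2 and 3 is argued against because their totals, 26979786 and 32260798 counts, were above the 24784738 and 23513921 of NAC73 1 and 4, and they held 9.01% of the 26965 replication counts that their depth would give. Root cap genes (mean log2 CPM 4.31 and 2.20 in NAC73 1 and 4 against -0.49 and -2.35 in NAC73 2 and 3) and stem cell niche genes (2.04 and 2.56 against 0.05 and -2.36) split the same way. In the CALS7 libraries root cap genes stood at 1.83 to 3.87 and niche genes at -1.82 to 1.25. For root cap genes NAC73 4 lay within that range, NAC73 1 above it and NAC73 2 and 3 below it. For niche genes NAC73 1 and 4 lay above the CALS7 range. Other kinds of root cells in NAC73 1 and 4 were not tested. The labels give no batch, and no explanation beyond those weighed here was tested.

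In 5 comparisons, none of the other splits among the 35 of the libraries gave as many genes called as the real one. The lowest share that 35 splits can give is 1 in 35. Splits that mix 2 lines widen the spread within groups, so the real split was likely to rank first and chance was not excluded. The real number and the highest of the other splits were 7142 and 0 for CVP2-DBOX against PEAR1, 9879 and 0 for CALS7 against PEAR1, 9363 and 2829 for NAC73 against CALS7, 12950 and 7325 for NAC57 against CALS7 and 9731 and 8807 for NAC57 against NAC73. In NAC57 against CALS7 and NAC57 against NAC73, the other splits that called many genes kept the 3 NAC57 libraries together, and so kept much of the real difference. In NAC73 against CALS7 some splits that mixed both lines also called many genes. A further structure among these libraries was not tested. The comparisons with PEAR1-DBOX (n = 2) were not split.

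Of 455 sets of 4 libraries tested, 37 had 1 library far from the other 3, where chance gives about 1 in 20, and genes of 1 library are not independent. PEAR1 1 was below the other 3 for UMAMIT28 (28.1 CPM), SIAR1 (290.4), AAE12 (18.1), SWEET11 (3.66), UMAMIT20 (18.5), AAH (11.9), GDU2 (10.6), AKN2 (22.7), AAE17 (93.9), SWEET12 (9.85), MYB28 (19.4), NAC086 (103.5) and SEOR1 (9.72), and above them for TCH3 (62.98). PEAR1 3 was below them for SOL1 (41.5 CPM), TOPII (73.7) and HCA2 (62.98). CVP2-DBOX 1 was below them for chr31 (73.1 CPM), and CVP2-DBOX 2 for EDA18 (89.2). CVP2-DBOX 2 was above them for TSO2 (177 CPM), PCNA2 (79.8), MCM5 (110.9) and ENP1 (AT1G31660, 140.0), and for the mean log2 CPM of the DNA replication list (5.97) and the ribosome biogenesis list (8.31). CVP2-DBOX 3 was below them for the A-type response regulator list (0.33). CALS7 2 was above them for EXT6 (117 CPM), PRP3 (166.1), HTB2 (13540), GATA5 (45.3), HTB11 (164.8) and NOP56 (84.4), and below them for TMO6 (363.7) and the pericycle list (-2.13). CALS7 1 was above them for the endodermis list (0.81). NAC73 1 was below them for CVP2 (136.5 CPM) and NAC028 (400.0). None of the 16 tests of depth and other library measures set a library apart.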

How the results depend on the processing

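The fits with NAC73 1 and 4 only, NAC73 2 and 3 only, and PEAR1 1 and 3 only were chosen after the result was seen, and the other settings were planned. Of 623 results on named genes, 565 kept their direction and side of the threshold with DESeq2, 536 with voom, 606 with no filter and 606 with median-of-ratios size factors. With only the 2 lines compared, 501 of 588 did. Of 119 list results, 71 kept theirs with an estimated correlation, where 48 were no longer called, and 103 with fry. With no filter and with median-of-ratios size factors, all 9 counts stayed within 1.5 times of the values reported. Depth limits genes with few counts, whose ratios carry wide counting intervals. The cause of the changes below was not tested.

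The count for PEAR1-DBOX vs PEAR1 was 1888 with DESeq2, 1471 with voom, 2419 with only the 2 lines and 26 with PEAR1 1 and 3 only. CVP2-DBOX vs PEAR1 had 15221 with voom and 12594 with only the 2 lines, NAC73 vs CALS7 2257 and NAC57 vs NAC73 5112 with only the 2 lines, and the genes enriched in 1 line numbered 1594 with PEAR1 1 and 3 only. The replicate numbers do not pair the libraries (mean correlation of residuals -0.18 to 0.04 for equal numbers and -0.01 to 0.03 for others), and with them as a block the count was 1161 for PEAR1-DBOX vs PEAR1 and 828 for CVP2-DBOX vs PEAR1-DBOX, while XCP2 turned to 6.38, XCP1 to 6.86 and the G2 and M phase list to -0.062 in the latter.

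With each library left out in turn, the count ranged from 30 to 1543 for PEAR1-DBOX vs PEAR1, 5496 to 6413 for CVP2-DBOX vs PEAR1, 1458 to 2818 for CVP2-DBOX vs PEAR1-DBOX, 8542 to 9200 for CALS7 vs PEAR1, 7306 to 9728 for NAC73 vs CALS7, 9386 to 13042 for NAC57 vs CALS7 and 8134 to 10810 for NAC57 vs NAC73. It ranged from 17854 to 20077 for genes differing among the 6 lines and from 2217 to 3107 for genes enriched in 1 line. Without PEAR1-DBOX 5, XCP2 (range -6.35 to 5.92), XCP1 (-5.64 to 6.48) and the G2 and M phase list (-0.077 to 1.11) turned in CVP2-DBOX vs PEAR1-DBOX. The test of the xylem list turned in PEAR1-DBOX vs PEAR1 without PEAR1-DBOX 3 (median -5.13 to -0.36), PRP3 in CALS7 vs PEAR1 without CALS7 2 (-8.40 to 2.75), and SKOR without NAC73 1 in NAC73 vs CALS7 (-6.54 to 2.40) and NAC57 vs NAC73 (-1.78 to 7.06). BBM turned to 4.69 with voom in NAC57 vs NAC73. With NAC73 2 and 3 only, BBM (9.76) and SKOR (7.11) turned in NAC57 vs NAC73, and in NAC73 vs CALS7 BBM (-5.27), CEL5 (-4.14), RNR1 (-0.0094), MCM5 (-0.15), FIB1 (-0.44) and BOP1 (-3.18).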

Other observations

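These single genes were not tested as a group. CLE5, which encodes a signalling peptide, was 958-fold lower in CVP2-DBOX than in PEAR1 (log2 -9.90 ± 1.30, SE, n = 4 each), and GDU3, a regulator of amino acid export, 316-fold lower (log2 -8.30 ± 1.16). CLE2, another peptide gene, was 266-fold lower in CALS7 than in PEAR1 (log2 -8.06 ± 1.37, n = 4 each) and 82.7-fold higher in the line labelled NAC57 than in CALS7 (log2 6.37 ± 1.31, n = 3 and n = 4). The amino acid transporter gene UMAMIT28 was 71.6-fold higher in the latter comparison (log2 6.16 ± 1.39), and DSEL, a lipase gene, 1164-fold lower (log2 -10.19 ± 1.26). The germin-like gene GLP10 rose 23.3-fold (log2 4.54 ± 0.55), MAP65-9, a microtubule-associated protein gene, 22.5-fold (log2 4.49 ± 0.49) and BXL2, a beta-xylosidase gene of the cell wall, 20.5-fold (log2 4.36 ± 0.90) in CALS7 against PEAR1. QRT3, a polygalacturonase gene, rose in NAC73 against CALS7 (log2 3.42 ± 0.96, n = 4 each; 2.71 and not called with NAC73 1 and 4 only), as did the histone variant gene HTA8 (log2 3.50 ± 0.49).

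WAVE2 was the 1 gene with 3 counts or fewer over a line and at least 10 CPM in each library of the other 5 lines, where it stood at 11.1 to 351 CPM. The correlation of library pairs across genes was 0.922 in PEAR1-DBOX, 0.947 to 0.966 in CVP2-DBOX, 0.967 to 0.976 in PEAR1, 0.969 to 0.971 in NAC57, 0.888 to 0.917 in CALS7 and 0.866 to 0.951 in NAC73 (Pearson's r of log2 CPM). Some library pairs of different lines were closer than pairs of the same line. PEAR1-DBOX 5 correlated at 0.939 to 0.953 with the PEAR1 libraries, above its 0.922 with PEAR1-DBOX 3. NAC73 1 correlated at 0.8995 with CALS7 2, above its 0.873 and 0.866 with NAC73 2 and 3. Genes are not independent replicates.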
